A study of Mus musculus with 6 samples.

How the data were processed

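Single-cell RNA sequencing was performed by the submitters on mouse bone marrow with the 10x Genomics 3′ reagent kit v2. Per the labels, the cells were sorted by flow cytometry from 3 compartments: LSK (lineage-negative, Sca-1 and Kit positive stem and progenitor cells), LK (Kit-positive, Sca-1-negative progenitors) and total haematopoietic cells. There were 6 libraries, 3 labelled as replicates of a Ptpn11 mutant genotype and 3 of the control genotype. How the 3 compartments were mixed in each library is not given in the sources used here, so the sort can set the share of any cell class. The labels do not say whether each replicate was a separate animal, so p-values measure the spread between these libraries.

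The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, which are not normalized, per the file headers and the labels. A second deposited table of the whole series holds UMI counts of the cells the authors kept. Cell Ranger 4.0.0 and Seurat 4.0 with the mouse build GRCm38 are named in the submitters' processing notes, with no role given for either tool. The filter behind the kept cells is not given in the sources used here. The table holds 29072 cells, each with 501 to 5792 genes detected and at most 4.99% mitochondrial UMIs, and 169 of 169 gene rows compared were equal to the matrices. Of the 32285 gene identifiers in the matrices, 32158 (99.6%) were found in the GENCODE M21 annotation of GRCm38, from which coordinates are given.

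The total count per library ran from 63179055 to 103767581 UMIs. The replicates of a group were distinct libraries, since their summed counts differed by 3.11 to 16.9 chi-square units per degree of freedom.

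The following choices were made before the data were examined: the cell set, the classes' markers, the gene lists, the tests, the rule for named genes and the alternatives, except where an item is said to have been added later. The cells the authors kept were used, after Scrublet (run within scanpy 1.11.5) had marked 46 of them as doublets, which were removed. Per library it marked 0.0195% to 0.799% of the kept cells, against 0.0998% to 2.90% of cells passing the own cell filter described below. Whether it failed on the kept cells, or doublets had been removed before deposit, was not tested. Doublets remain a possible source of mixed expression. Counts were scaled to 10000 per cell and log-transformed. Then 2000 variable genes ranked across libraries, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 gave 26 clusters of 29026 cells, without batch correction. Immunoglobulin and T cell receptor variable genes and the sex-linked genes were left out of the clustering.

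A cluster was named from the fixed markers, and the scoring rule for this was set after the clusters were seen. The class with the highest mean standardised marker level gave the name. It needed at least 3 markers detected in a share of at least 0.1 of the cells, at least 1 of its markers among the cluster's 10 leading genes by fold, and no more markers of another class there. Class names end in "-like" because they rest on these markers. HSC/MPP-like cells (haematopoietic stem cells and multipotent progenitors) were clusters 0, 2, 7 and 16. Cluster 0 was led by Hlf, Procr and Ly6a, cluster 2 by Ung, Tespa1, Adgrl4, Hbb-bt, Gem and Selp, cluster 7 by Dntt, Hbb-bt and Flt3, and cluster 16 by Meg3, Mllt3 and Procr. Several of these leading genes also differed between genotypes, so the clustering was repeated without every gene called in these cells. GMP-like cells (granulocyte-monocyte progenitors) were clusters 1, 8 and 9, led by Mpo, Elane, Irf8 and Ms4a3. Monocyte-like cells were clusters 10 and 17 (Ctss, Ccr2, Fn1, Klf4), and neutrophil-like cells clusters 4, 5 and 15 (Ltf, Ngp, Retnlg, Fcnb). Megakaryocyte-like clusters were led by Pf4 and Itga2b, the megakaryocyte-erythroid progenitor (MEP)-like cluster by Car1 and Klf1, and the erythroblast-like cluster by Car1 and Hba-a1. Pro-B/pre-B cell-like, B cell-like, plasma cell-like and basophil/mast cell-like clusters were led by Vpreb3, Cd79a, Jchain and Prss34 in that order. Clusters 3 (histone genes), 6 (Ube2c, Cenpf), 18 (Dntt, Flt3), 21 (Ccl5, Trbc2), 23 (Cd74, Siglech) and 24 (Ifit1, Isg15) stayed unnamed.

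UMI counts were summed per library and class, and libraries with at least 20 cells of a class entered its test. Mutant and control sums were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test, two-sided). P-values were adjusted by Benjamini-Hochberg over the genes tested in a class, with a threshold of 0.05. Every adjusted p printed for a gene comes from that fit unless another tool is named. Fold changes are log2 of mutant over control with their standard error (SE), and levels are CPM (counts relative to the scaled library total), as mean ± SD over 3 libraries per group, except that 2 mutant libraries entered for pro-B/pre-B cell-like cells and cluster 21. Gene lists were tested on voom values of the same sums with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over the lists of a class. There were 34 fixed lists and 2 made by name pattern, for cytosolic ribosomal proteins and nuclear-encoded oxidative phosphorylation. Pseudogenes and S6 kinases that the ribosomal pattern also matched were left out, a refinement made after the pattern was fixed. Differences between HSC/MPP-like and GMP-like effects were tested with limma on the difference of log2 CPM within each library, with a prior count of 2. Class shares were compared by an exact two-sided permutation test, whose smallest p for 3 libraries against 3 is 0.1. Intervals of shares are exact binomial 95% intervals and cover counting error only.

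The rule for named genes took Ptpn11 first, then the 6 highest and 6 lowest log2 fold changes of a main class (3 and 3 in other classes). These had an adjusted p under 0.05, a mean of at least 20 CPM and no overlap between groups. Immunoglobulin, T cell receptor, sex-linked and predicted genes were not named. Up to 3 members with the smallest p came from each list that passed or had a passing member. In HSC/MPP-like cells all tested members of the fetal list and Cd52 were added. The text gives a part of these genes, picked after their values were seen, and some of them are not reported here.

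Alternatives were DESeq2 1.42.0, RLE scaling, no count filter, a replicate block, each library left out in turn, an own cell filter (at least 1000 UMIs, 500 genes and under 10% mitochondrial UMIs), doublets kept, Leiden resolutions 0.5 and 2, and sums without haemoglobin, granule and immunoglobulin genes. For lists they were camera with an estimated correlation and fry, for shares edgeR on cell counts and a denominator without erythroblast-like cells, and for the class difference a prior count of 0.5. Added after seeing the data were a covariate marking the libraries without Xist (under 10 CPM), removal of the 5% highest doublet scores per library, parts of the HSC/MPP-like and monocyte-like classes, HSC/MPP-like cells with clusters 3 and 6, the own cell filter for lists and for the class difference, and clustering without the genes called in HSC/MPP-like cells.

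The edgeR, DESeq2, limma and camera steps were checked on simulated counts, drawn from the real means and library sizes, with 200 genes changed by known folds. In the HSC/MPP-like simulation edgeR recovered 58.2%, 92.5% and 98.5% of genes changed 1.5-fold, 2-fold and 3-fold. For GMP-like cells these values were 67.2%, 94% and 98.5%, for monocyte-like cells 14.9%, 61.2% and 92.4%, for neutrophil-like cells 31.3%, 71.6% and 92.4%, and for megakaryocyte-like cells 56.7%, 88.1% and 97%. The limma test of the class difference recovered 1.49%, 61.2% and 93.9%. A simulated list raised 1.5-fold was called by camera, with 0 of the other lists called. The simulated genes were drawn independently, so this check could not show list calls that come from correlation between genes. Further computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.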

Results

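Bone marrow cells were profiled by single-cell RNA sequencing in 3 mutant and 3 control libraries, 18 weeks after tamoxifen. The mutant libraries carry the Ptpn11 E76K allele in the heterozygous state together with an inducible Cre driven by the Scl gene, and the control libraries carry the Cre with wild-type Ptpn11. Ptpn11 encodes the phosphatase SHP2, which promotes RAS-MAPK signalling, and the series is about juvenile myelomonocytic leukaemia. Control replicates 1, 2 and 3 held 5797, 6456 and 4188 barcodes with 87819065, 91401325 and 63179055 UMIs. Mutant replicates 1, 2 and 3 held 5643, 6294 and 6043 barcodes with 101984199, 95024738 and 103767581 UMIs. The authors kept 4827, 5697 and 3628 control cells and 4641, 5118 and 5161 mutant cells. Median UMIs of the kept cells were 13189, 10864 and 11565 in the control libraries and 17801, 15052 and 16472 in the mutant libraries. In GMP-like cells Xist, the RNA of the inactive X chromosome, had 493 CPM in control replicate 1, 0.295 and 0.492 CPM in control replicates 2 and 3, and 472, 585 and 505 CPM in the mutant libraries. The Y-linked gene Eif2s3y had 50.1 and 49.7 CPM in control replicates 2 and 3 and 0 CPM in the 4 others, so sex-linked expression differs between the genotype groups.

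The first comparison asks whether the cell classes took different shares of the marrow sample. Among the kept cells GMP-like cells made up 14.2% ± 2.37 (SD, n = 3) of control and 21.2% ± 2.84 (n = 3) of mutant cells, with no overlap between the groups (exact two-sided permutation p = 0.1, adjusted p = 0.24). Monocyte-like cells made up 4.26% ± 2.28 of control and 7.35% ± 1.41 of mutant cells (exact p = 0.2). Pro-B/pre-B cell-like cells made up 2.01% ± 0.333 and 1.01% ± 0.621, and B cell-like cells 1.2% ± 0.83 and 0.198% ± 0.182 (both exact p = 0.1). Neutrophil-like cells made up 18.0% ± 0.128 and 15.8% ± 1.79 (exact p = 0.1), and plasma cell-like cells 0.156% ± 0.0989 and 0.0676% ± 0.0251 (exact p = 0.1). HSC/MPP-like cells made up 29.1% ± 5.48 and 23.4% ± 4.53 (exact p = 0.3), and megakaryocyte-like cells 6.15% ± 1.30 and 8.13% ± 0.845 (exact p = 0.2). MEP-like, erythroblast-like and basophil/mast cell-like shares had exact p of 0.3, 0.4 and 0.4, and the unnamed clusters together held 18.3% of control and 15.9% of mutant cells. None of these tests can go below 0.1 with 3 libraries against 3, and edgeR on the cell counts called 0 of 12 shares, with 2 at an unadjusted p under 0.05. Leaving out 1 library moved some differences between mutant and control shares by over 1.5 times. In percentage points, the HSC/MPP-like difference of -5.72 was -8.88 without control replicate 1 and -3.46 without mutant replicate 3, and the neutrophil-like difference of -2.19 was -1.30 without mutant replicate 2. The B cell-like and plasma cell-like differences were -0.548 and -0.0318 without control replicate 1, and the pro-B/pre-B cell-like difference was -0.664 without mutant replicate 2. The share of each class also depends on how the LSK, LK and total sorts were mixed.

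**Figure D1:**
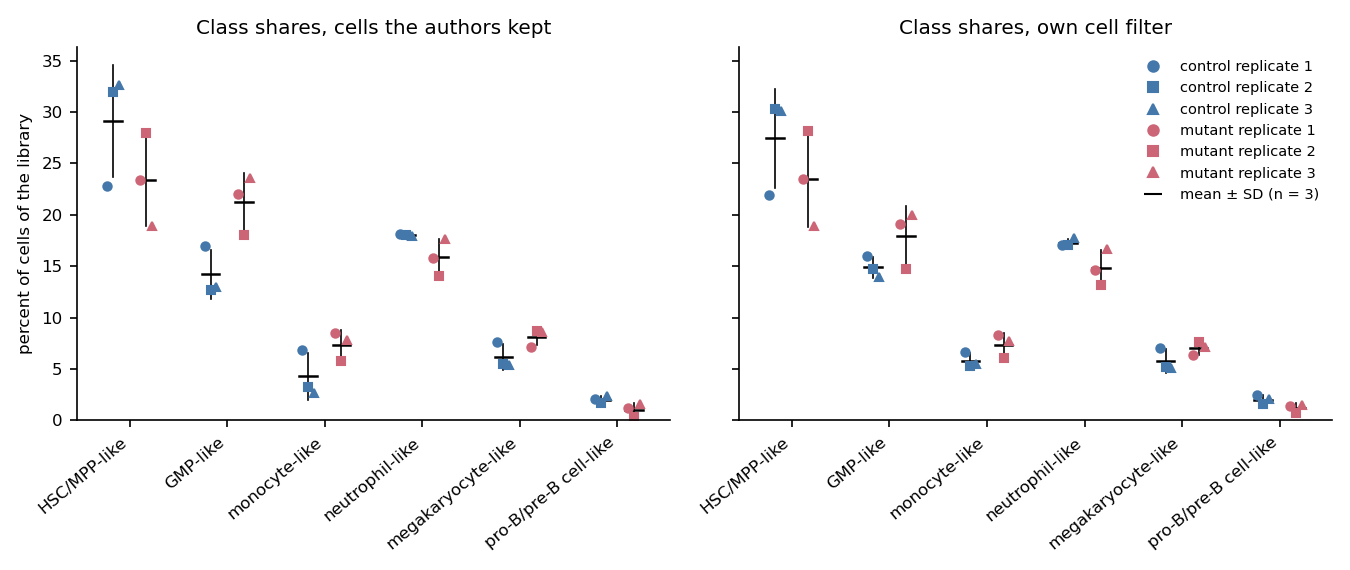
Percent of cells per library (y axis) in 6 classes (x axis), among the cells the authors kept and among cells passing the own cell filter, with blue control and red mutant points, a shape per replicate, and black lines for mean ± SD (n = 3). GMP-like shares do not overlap among the kept cells and overlap with the own cell filter.

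The kept cells lacked cells of several classes unevenly between libraries. With the own cell filter, a monocyte-like cluster was found in every library, and of its cells within the ranges of the kept cells the deposited table lacked 93.4% (exact 95% interval 86.9 to 97.3) in control replicate 2 and 97.6% (91.5 to 99.7) in control replicate 3. It lacked 11.8% in control replicate 1 and 10.8%, 22.2% and 10.6% in the mutant libraries. For a GMP-like cluster the table lacked 71.0% and 60.3% in control replicates 2 and 3, 3.9% in control replicate 1 and 0.939% to 2.94% in the mutant libraries. An immature neutrophil-like cluster led by Fcnb and Chil3 lacked 19.4% and 41.9% of its cells in control replicates 2 and 3. Its loss was 2.46% in control replicate 1 and 0.61%, 0% and 0% in mutant replicates 1, 2 and 3. Of a pro-B/pre-B cell-like cluster it lacked 21.8%, 2.13% and 0% in control replicates 1, 2 and 3 and 24.3%, 51.4% and 4.76% in mutant replicates 1, 2 and 3, and with the own cell filter that share was 2.02% ± 0.442 and 1.19% ± 0.464 (exact permutation p = 0.1, n = 3 each). Of a basophil/mast cell-like cluster it lacked 50.8% in control replicate 1 and 42.5% in mutant replicate 3, against 2.04% to 15.5% in the 4 other libraries. With the own cell filter the GMP-like share was 14.9% ± 1.02 of control and 17.9% ± 2.86 of mutant cells (exact permutation p = 0.3, n = 3 each) and the monocyte-like share 5.78% ± 0.755 and 7.35% ± 1.16 (exact p = 0.2).

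**Figure D2:**
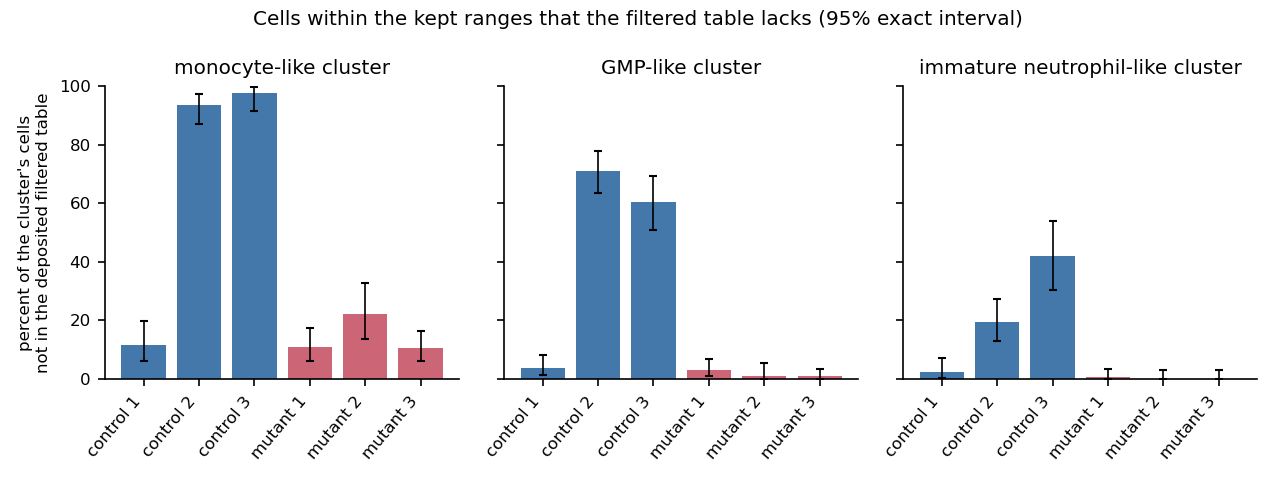
Percent of the cells of monocyte-like, GMP-like and immature neutrophil-like clusters that lie within the ranges of the kept cells but are lacking in the deposited filtered table (y axis), per library (x axis), with exact 95% intervals. Control replicates 2 and 3 lie above the 4 other libraries in all 3 clusters.

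The second comparison asks which genes differ between mutant and control HSC/MPP-like cells. Ptpn11 (ENSMUSG00000043733, chromosome 5, 121130533 to 121191397 of GRCm38, protein-coding) had 23.7 ± 3.38 CPM in control and 24.8 ± 2.05 CPM in mutant libraries (log2 fold change 0.06, SE 0.119, adjusted p = 0.75, n = 3 each). Tags at the 3′ end do not show the allele, so this value does not check the labels, and it turned to log2 -0.021 without control replicate 3 and -0.14 with the Xist-negative libraries marked by a covariate. The adult beta-globin gene Hbb-bt (ENSMUSG00000073940, chromosome 7, 103812524 to 103813996) rose from 36.9 ± 14.6 to 506 ± 71.4 CPM (log2 3.78, SE 0.234, adjusted p = 2.92e-05), and tags may be shared with its paralog Hbb-bs. Gem (ENSMUSG00000028214, chromosome 4, 11704457 to 11714752), a small GTPase of the RGK family, rose by a log2 fold change of 3.48 (SE 0.196, adjusted p = 2.29e-05) to 149 ± 42.7 CPM. Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925), the G1-phase cyclin D1, rose from 21.2 ± 8.11 to 70.5 ± 1.76 CPM (log2 1.74, SE 0.199, adjusted p = 9.66e-04). Selp (P-selectin), Lgals1 (galectin-1) and Ms4a3 (a granulocyte-monocyte progenitor gene) rose by log2 1.72 (SE 0.155), 1.64 (SE 0.132) and 1.5 (SE 0.216). Procr (ENSMUSG00000027611, chromosome 2, 155751117 to 155755471), the endothelial protein C receptor found on stem cells, fell by 2.07 on the log2 scale (SE 0.225, adjusted p = 6.84e-04) from 45.0 ± 14.4 to 10.7 ± 1.5 CPM. Ifitm1 (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), an interferon-inducible membrane protein, fell by 2.06 (SE 0.218, adjusted p = 5.94e-04) from 1366 ± 234 to 328 ± 120 CPM. Tnfsf13os, which overlaps Tnfsf13, Serpinf1 and Maged1 fell by 2.01 (SE 0.115), 1.80 (SE 0.175) and 1.75 (SE 0.163).

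**Figure D3:**
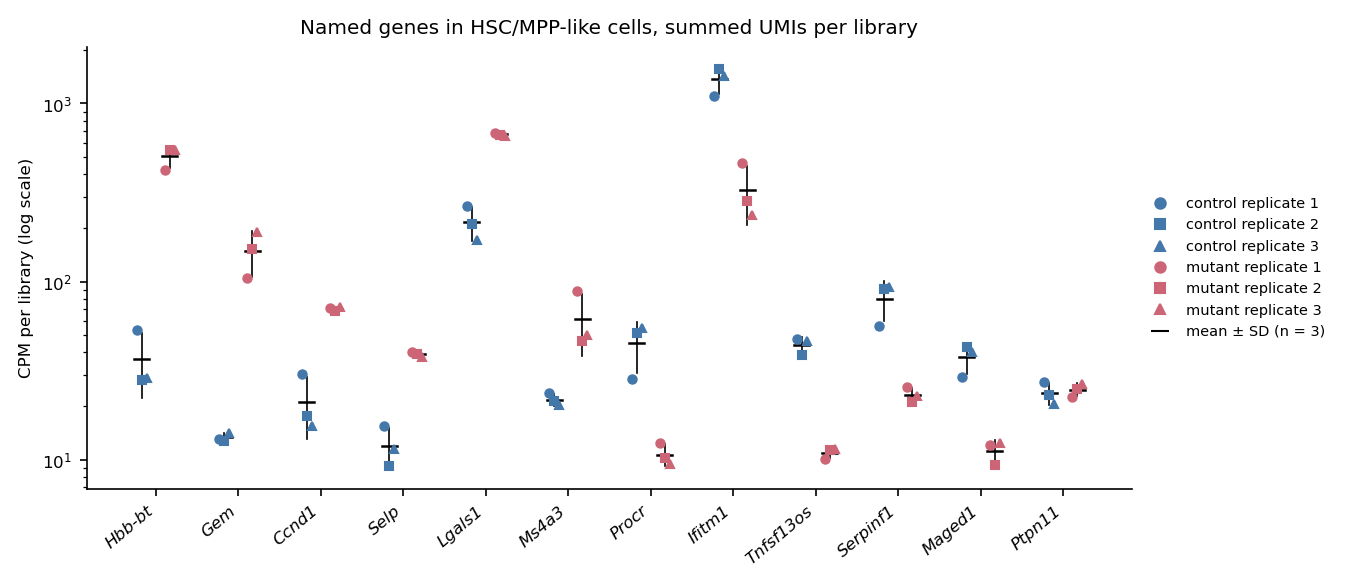
CPM in HSC/MPP-like cells (y axis, log scale) for each library of control and mutant, for Ptpn11 and genes from among the highest and lowest fold changes. Hbb-bt lies at a mean of 36.9 CPM in control and 506 CPM in mutant libraries, and Ptpn11 at 23.7 and 24.8 CPM.

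In all, 1684 of 12144 genes passed in HSC/MPP-like cells, 745 higher and 939 lower in the mutant, against 1757 by DESeq2 (985 higher, 772 lower), of which 1412 were shared. The clusters took different shares of the class in the groups: cluster 0 held 45.8% to 57.1% of it in control and 24.6% to 33.5% in mutant libraries, and cluster 2 held 13.5% to 33.4% and 37.7% to 49.1%. Cluster 16 held 6.54% to 13.4% of it in control and 0.552% to 0.924% in mutant libraries, or 3.35% ± 1.61 and 0.16% ± 0.0265 of all kept cells (exact permutation p = 0.1, n = 3 each). Procr leads clusters 0 and 16, Hbb-bt, Gem and Selp lead cluster 2 and Hbb-bt also leads cluster 7, while Procr and Ifitm1 are also markers of the class. With all called genes left out of the clustering 1961 genes passed, 1585 of them also called above. In that clustering the cluster with the highest HSC/MPP marker score held 11.5%, 18.7% and 20.5% of the cells in control replicates 1, 2 and 3. It held 7.80%, 12.9% and 7.41% in mutant replicates 1, 2 and 3, so the groups overlapped. With the clusters of the main clustering, 159 genes passed in cluster 0 alone, 261 in cluster 2 alone and 1048 without cluster 16. The count was 4494 without control replicate 1, 362 and 511 without control replicates 2 and 3, and 473, 652 and 436 without mutant replicates 1, 2 and 3. With the Xist-negative libraries marked by a covariate it was 335, of which 289 were also called above, and the genotype effect then rests on control replicate 1 against the mutant libraries.

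Of the 34 lists tested in HSC/MPP-like cells 16 were called by camera with a preset correlation, 8 higher and 8 lower, and 0 with an estimated correlation. Of 19 measured targets of MAPK signalling 8 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0017, and adjusted p = 0.321 with an estimated correlation). Etv4, an ETS transcription factor, had 5 UMIs in control and 346 in mutant libraries (log2 6.01, SE 0.416, adjusted p = 7.09e-05), and Dusp6, an ERK phosphatase, rose by log2 1.18 (SE 0.0995, adjusted p = 1.67e-04). Of 80 cytosolic ribosomal protein genes 45 rose and 0 fell (59 and 0 adjusted over the list alone; camera adjusted p = 5.17e-20, and adjusted p = 0.321 with an estimated correlation), such as Rpl27 (log2 0.29, SE 0.0508). Oxidative phosphorylation genes rose in 25 of 86 (54 and 1 fallen adjusted over the list alone; 6.69e-17) and MYC and ribosome biogenesis genes in 18 of 31 (25 adjusted over the list alone; 4.42e-13), with none fallen over all genes, and both lists had an adjusted p = 0.505 with an estimated correlation. Examples are Ndufa4 (log2 0.64, SE 0.0896), a respiratory chain subunit, and Npm1 (0.42, SE 0.0841), a nucleolar protein. G2/M genes rose in 15 of 35 (23 adjusted over the list alone; 4.36e-11), S-phase genes in 9 of 32 (21; 3.37e-10) and glycolysis genes in 5 of 17 (8; 0.0107). Cenpa, a centromeric histone, rose by log2 1.03 (SE 0.0961), Rrm2, a ribonucleotide reductase subunit, by 0.51 (SE 0.109) and Pgk1 by 0.43 (SE 0.0824). These 3 lists also had an adjusted p = 0.505 with an estimated correlation. Primary granule genes rose in 4 of 14 (4 adjusted over the list alone; 0.0487, and adjusted p = 0.6 with an estimated correlation), and were not called as a list with the own cell filter (0.0918), without mutant replicate 1 (0.303), without cluster 16 (0.271) or in cluster 0 alone.

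Lists of stem cell, imprinted and stress genes were called lower with the preset correlation. None was called with an estimated correlation, where the imprinted list had an adjusted p = 0.46, the cholesterol list 0.6 and the 6 other lists here 0.505. Of 26 self-renewal genes 10 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 5.76e-07), among them Mllt3, which maintains stem cells (log2 -0.98, SE 0.114). Of 12 imprinted genes 9 fell and 0 rose (9 and 0 adjusted over the list alone; 2.38e-06), among them the signalling adaptor Grb10 (log2 -2.02, SE 0.222) and Phlda2 (-1.09, SE 0.134), while Snrpn, which overlaps Snurf, had 68 UMIs in control and 3 in mutant libraries (adjusted p = 0.00142). Of 18 megakaryocyte priming genes 9 fell and 1 rose (10 and 2 adjusted over the list alone; 0.00211), among them Vwf, the von Willebrand factor (log2 -2.32, SE 0.306). Of 19 quiescence genes 7 fell and 1 rose (10 and 2; 0.0239), among them Cdkn1c, a cyclin-dependent kinase inhibitor (-1.43, SE 0.204). Of 12 STAT5 targets 5 fell and 2 rose (7 and 2; 0.0126), among them the cytokine signalling inhibitors Socs2 (-2.96, SE 0.247) and Cish (-1.35, SE 0.166). Of 20 dissociation stress genes, which respond to handling of cells, 10 fell and 2 rose (13 and 3; 3.69e-04), among them the immediate early genes Fos (-1.63, SE 0.201) and Junb (-1.01, SE 0.169). Of 16 granulocyte-monocyte priming factors 5 fell and 1 rose (6 and 2; 0.0302), among them Gfi1 (-1.23, SE 0.192). Of 22 cholesterol synthesis genes 0 passed (0 adjusted over the list alone; 0.00246). Without cluster 16 the megakaryocyte priming, quiescence and STAT5 lists were not called (adjusted p = 0.0766, 0.0766 and 0.07). In cluster 0 alone the STAT5 and cholesterol lists were not called (0.25 and 0.0809), and the self-renewal, quiescence and megakaryocyte priming lists turned upward without being called (0.845, 0.876 and 0.704). The priming factor and cholesterol lists were not called with the Xist-negative libraries marked (0.388 and 0.657) or without mutant replicate 2 (0.0765 and 0.0647).

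**Figure D4:**
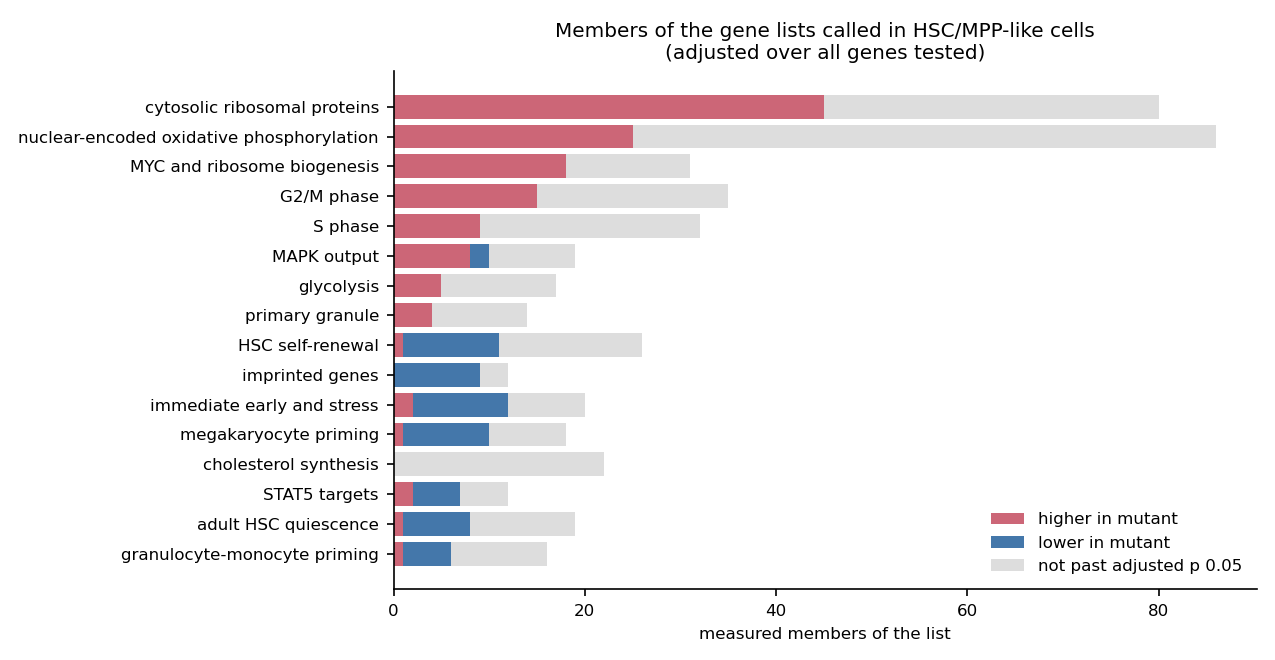
Number of measured members (x axis) of each list called in HSC/MPP-like cells (y axis) that were higher, lower or not past the threshold in the mutant. The ribosomal list has 45 of 80 members higher and the imprinted list 9 of 12 lower.

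Mllt3 was at log2 0.435 in cluster 0 alone, 0.29 in cluster 2 alone and -0.13 without cluster 16, where Vwf was also not called (log2 -1.15, adjusted p = 0.117). Rrm2 was at log2 -0.78 in cluster 0 alone and -0.18 in cluster 2 alone, and in cluster 0 the S-phase and G2/M lists were called lower (adjusted p = 3.75e-09 and 0.044) and the glycolysis list was not called (0.905). With the Xist-negative libraries marked, the members that passed fell to 9 ribosomal, 1 oxidative phosphorylation, 1 MYC, 4 G2/M and 0 S-phase genes higher, and 8 self-renewal and 6 imprinted genes lower. The list medians were smaller there and kept their direction. Without and with the covariate they were log2 0.157 and 0.139 for ribosomal, 0.251 and 0.104 for oxidative phosphorylation and 0.435 and 0.188 for MYC genes. They were 0.466 and 0.204 for G2/M, 0.306 and 0.125 for S-phase, -0.361 and -0.209 for self-renewal and -1.13 and -0.88 for imprinted genes. Of the named members, Rrm2 and Pgk1 then had adjusted p = 0.18 and 0.0605, and without control replicate 2 Rpl27, Npm1, Rrm2 and Pgk1 had adjusted p from 0.0528 to 0.0843. Without mutant replicate 1 or 3 Npm1, Rrm2 and Pgk1 were not called (adjusted p from 0.0539 to 0.0742), nor was Rrm2 without control replicate 3 (0.0625). In cluster 0 alone Ms4a3, Cdkn1c, Cish, Grb10, Phlda2, Ndufa4, Npm1, Cenpa and Pgk1 were not called, in cluster 2 alone Cdkn1c, Cish, Grb10, Phlda2 and Pgk1 were not, and with clusters 3 and 6 added Cenpa was not. Of 27 therapy targets on the cell surface 6 rose and 1 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.397), and Cd52 rose from 367 ± 34.9 to 535 ± 30.7 CPM (log2 0.55, SE 0.0838, adjusted p = 0.0037). Cd52 was not called in cluster 0 alone (log2 0.2, adjusted p = 0.482) or cluster 2 alone (log2 0.26, adjusted p = 0.114). Of 4 measured haemoglobin genes, too few for camera, 1 rose, which was Hbb-bt (1 rose and 1 fell adjusted over the list alone), and 0 of 18 secondary granule genes passed.

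Fetal stem cell genes were compared because the series title speaks of oncofetal reprogramming. The fixed fetal list has 19 genes, of which only 7 were tested in HSC/MPP-like cells, so what follows covers those 7. Of these, 0 rose and 1 fell (0 and 1 adjusted over the list alone, and camera adjusted p = 0.572). The RNA-binding protein genes Igf2bp2 and Igf2bp3 had log2 fold changes of 0.12 (SE 0.228, adjusted p = 0.758) and -0.39 (SE 0.166, adjusted p = 0.131). The chromatin protein genes Hmga2 and Hmga1 had 0.03 (SE 0.274, adjusted p = 0.952) and 0.08 (SE 0.0997, adjusted p = 0.634), the transcription factor gene Arid3a 0.08 (SE 0.179, adjusted p = 0.802) and the glypican gene Gpc3 -0.55 (SE 0.328, adjusted p = 0.269), which passed only with clusters 3 and 6 added (log2 -1.2, adjusted p = 0.0228). Dlk1, an imprinted membrane protein gene, was called lower (log2 -1.05, SE 0.286, adjusted p = 0.0379) on 76 UMIs in control and 36 in mutant libraries. That call was lost with DESeq2 (adjusted p = 0.127), with the Xist-negative libraries marked (adjusted p = 0.416), without cluster 16 (adjusted p = 0.369), without the highest doublet scores (adjusted p = 0.0867), and without any single library other than control replicate 1, without which Igf2bp3 also passed (log2 -0.46, adjusted p = 0.0413). The median of the list was 0.0319 and its mean -0.241. In simulated HSC/MPP-like counts edgeR recovered 58.2% of genes changed 1.5-fold and 92.5% of those changed 2-fold. Those genes were drawn at random from all genes tested, with the same dispersion for each. The rates therefore need not hold for the fetal members, whose SE ran up to 0.328, and a change of that size in them may be missed.

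The third comparison asks which genes differ in GMP-like cells, the progenitors of granulocytes and monocytes. Cluster 1 held 42.7% to 58.9% of them in control and 42.5% to 48.8% in mutant libraries. Ptpn11 had a log2 fold change of 0.16 (SE 0.107, adjusted p = 0.615, n = 3 each). Ccnd1 rose from 10.5 ± 2.37 to 34.8 ± 0.824 CPM (log2 1.72, SE 0.133, adjusted p = 7.18e-04), and Selp by log2 2.61 (SE 0.118, adjusted p = 8.68e-06). S100a6, a calcium-binding protein gene, rose by log2 1.2 (SE 0.13, adjusted p = 0.00269) and Ifi27l2a, an interferon-inducible gene with a close paralog Ifi27l2b, by 1.15 (SE 0.162, adjusted p = 0.0165). Tnfsf13, the cytokine APRIL, fell by 1.12 on the log2 scale (SE 0.113, adjusted p = 0.00165) from 84.4 ± 14 to 38.9 ± 2.71 CPM, and Il11ra1, an interleukin-11 receptor gene with close paralogs, fell by 0.59 (SE 0.07, adjusted p = 0.00565). Camp, an antimicrobial granule protein gene, rose by log2 0.83 (SE 0.129, adjusted p = 0.027) among the kept cells but was at log2 -0.55 with the own cell filter. In all, 51 of 11797 genes passed, 37 higher and 14 lower, and DESeq2 called 176 (109 higher, 67 lower). The kept cells of control replicates 2 and 3 lack 71.0% and 60.3% of a GMP-like cluster, as given above. With the own cell filter 60 genes passed, 38 higher and 22 lower, of which 37 were also called among the kept cells. The count was 748 without control replicate 1, 24 and 27 without control replicates 2 and 3, 33, 25 and 17 without mutant replicates 1, 2 and 3, and 37 with the Xist-negative libraries marked. Ccnd1, S100a6, Tnfsf13 and Selp passed in each of these left-out fits. Ifi27l2a was not called with the covariate (adjusted p = 0.0721), and neither Ifi27l2a nor Camp was called without control replicate 3, mutant replicate 1 or mutant replicate 3 (adjusted p from 0.0658 to 0.137), nor was Camp without the highest doublet scores (adjusted p = 0.0868). Il11ra1 was not called without mutant replicate 3 (adjusted p = 0.0613).

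Targets of MAPK signalling also rose in GMP-like cells, in 4 of 17 members with 0 fallen (9 and 1 adjusted over the list alone; camera adjusted p = 1.81e-06, and adjusted p = 0.334 with an estimated correlation). Etv4 had 2 UMIs in control and 267 in mutant libraries (adjusted p = 7.56e-04), and Dusp6 rose by log2 1.15 (SE 0.116, adjusted p = 0.00165). Monocyte genes rose in 2 of 23 (8 adjusted over the list alone; 3.2e-09, and adjusted p = 0.519 with an estimated correlation), among them Lgals3, the gene of galectin-3 (log2 1.48, SE 0.135). Type I interferon genes rose in 2 of 26 (2; 1.77e-06, and adjusted p = 0.578 with an estimated correlation), but with the Xist-negative libraries marked the list was not called (adjusted p = 0.121) and 0 members passed. Among the members was Usp18, an inhibitor of interferon signalling (log2 1.54, SE 0.266). Basophil and mast cell genes rose in 1 of 10 (8, with 1 fallen, adjusted over the list alone; 1.23e-06, and adjusted p = 0.334 with an estimated correlation), namely Cd200r3, with 5 UMIs in control and 110 in mutant libraries. Usp18 and Cd200r3 were not called with the Xist-negative libraries marked (adjusted p = 0.229 and 0.0601), nor without control replicate 2, control replicate 3 or mutant replicate 3. Usp18 was also not called without mutant replicate 1, nor Cd200r3 without mutant replicate 2, and Lgals3 was not called without the highest doublet scores (log2 0.53, adjusted p = 0.0868). Leiden resolution 0.5 and the removal of the highest doublet scores also ended the call of Usp18 (adjusted p = 0.125 and 0.054), as did Leiden resolution 2 and keeping doublets that of Cd200r3 (adjusted p = 0.201 and 0.062). G2/M and MYC lists were called higher with 0 members past the threshold over all genes (15 of 35 and 2 of 31 adjusted over the list alone; 2.16e-16 and 7.58e-09, and adjusted p = 0.4 and 0.578 with an estimated correlation), and the MYC list was not called with the Xist-negative libraries marked (adjusted p = 0.497). The B cell list was called lower with 1 of 7 fallen (1 adjusted over the list alone; 0.0304, and adjusted p = 0.519 with an estimated correlation), beside a B cell-like share of 1.2% in control and 0.198% in mutant libraries, and was not called without control replicate 1 (adjusted p = 0.133) or mutant replicate 2 (0.197). In all 12 of 32 lists were called, 9 higher and 3 lower, and 0 with an estimated correlation.

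Whether the effect in HSC/MPP-like cells differed from that in GMP-like cells was tested by limma on the difference within each library. Of 11388 genes 0 passed, with 2395 at an unadjusted p under 0.05, and no second tool was run. Without control replicate 1, 765 genes passed (487 with the higher and 278 with the lower difference in the mutant). In simulated data the test recovered 1.49%, 61.2% and 93.9% of genes changed 1.5-fold, 2-fold and 3-fold in HSC/MPP-like cells alone.

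The fourth comparison concerns monocyte-like cells, of which the kept cells of control replicates 2 and 3 lack most of a cluster as given above. Cluster 17 held 29.2%, 3.83% and 0% of the class in control replicates 1, 2 and 3 and 23.7% to 35.4% in mutant libraries. No gene was called: edgeR called 0 of 8860 genes, with 876 at an unadjusted p under 0.05, and DESeq2 called 17. Ptpn11 had a log2 fold change of -0.11 (SE 0.245, adjusted p = 0.89, n = 3 each). Id2, an inhibitor of basic helix-loop-helix factors, had a log2 fold change of -1.06 (SE 0.138, adjusted p = 0.156), and Ifi27l2a 0.58 (SE 0.108, adjusted p = 0.38), and DESeq2 called both, as did edgeR without control replicate 1 or without a count filter. Id2 also passed with the own cell filter, with the Xist-negative libraries marked and in cluster 10 alone. Ccnd1 had 3 UMIs in control and 68 in mutant libraries (adjusted p = 0.38), and passed without control replicate 1, without a count filter, with the own cell filter and without the highest doublet scores. Without control replicate 1, 1270 genes passed, with the own cell filter 25 and with the Xist-negative libraries marked 13. MYC genes were called higher as a list of 29 (16 adjusted over the list alone, 0 over all genes; camera adjusted p = 9.46e-16, and adjusted p = 0.484 with an estimated correlation), and type I interferon genes as a list of 28 (1 adjusted over the list alone; 0.00279, and adjusted p = 0.625 with an estimated correlation). The interferon list was not called without control replicate 1, control replicate 2 or mutant replicate 2 (adjusted p = 0.0553, 0.0563 and 0.0706). The monocyte list of 26 was called lower (3 adjusted over the list alone; 0.00124, and adjusted p = 0.541 with an estimated correlation), but not with the own cell filter (adjusted p = 0.445) or with the Xist-negative libraries marked (0.0784). The S-phase list was called higher among the kept cells (1.25e-13, and adjusted p = 0.541 with an estimated correlation) and lower with the own cell filter (adjusted p = 0.0197), and was not called with the Xist-negative libraries marked (0.632). In all 15 of 29 lists were called, 10 higher and 5 lower, and 0 with an estimated correlation. In simulated monocyte-like counts edgeR recovered 14.9%, 61.2% and 92.4% of genes changed 1.5-fold, 2-fold and 3-fold.

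The fifth comparison concerns neutrophil-like cells. Their clusters took different shares of the class: the mature cluster 5 held 44.3% to 46.2% of it in control and 24.3% to 41.3% in mutant libraries, and the immature cluster 15 held 10.1% to 13.8% and 14.1% to 23.3%, and the comparison was not made within a cluster. The kept cells of control replicates 2 and 3 lack 19.4% and 41.9% of an immature neutrophil-like cluster, as given above. How far this loss lowers the immature share of those controls was not tested. Wfdc17, a whey acidic protein family gene, fell by 4.04 on the log2 scale (SE 0.298, adjusted p = 1.17e-04), from 744 ± 330 to 45.2 ± 1.88 CPM (n = 3 each). Ifitm1 fell by 3.06 (SE 0.281, adjusted p = 6.47e-04), from 660 ± 269 to 78.9 ± 17.5 CPM. Fabp5, a fatty acid-binding protein gene, fell by 0.91 (SE 0.114, adjusted p = 0.012), and that call was lost without each mutant library in turn and with the Xist-negative libraries marked (adjusted p = 0.12). The fourth called gene, 1700006J14Rik, is outside the naming rule and was picked after its values were seen, and it rose by log2 2.38 (SE 0.336, adjusted p = 0.0282). It was the only higher call, and 0 genes were called higher without control replicate 2, mutant replicate 1 or mutant replicate 2, while with the Xist-negative libraries marked it had an adjusted p = 0.221. Ptpn11 had a log2 fold change of 0.10 (SE 0.174, adjusted p = 0.826). In all 4 of 8601 genes passed, 1 higher and 3 lower, and DESeq2 called 50 (20 higher, 30 lower). The count was 184 without control replicate 1, 7 without control replicate 2 or 3, 2 without mutant replicate 2 and 11 with the Xist-negative libraries marked. G2/M genes were called higher as a list of 35 (22 adjusted over the list alone, 0 over all genes; camera adjusted p = 1.4e-17, and adjusted p = 0.45 with an estimated correlation). Primary granule genes were called higher as a list of 13 (9 adjusted over the list alone; 2.01e-06, and adjusted p = 0.45 with an estimated correlation) but not with the own cell filter (adjusted p = 0.687). The ribosomal list was called higher (4.84e-09, and adjusted p = 0.703 with an estimated correlation) and lower with the own cell filter (adjusted p = 0.0022). B cell genes were called lower, with all 6 measured members past the threshold adjusted over the list alone (5.49e-05, and adjusted p = 0.314 with an estimated correlation), beside the lower B cell-like share. Of the 29 lists tested 13 were called, 6 higher and 7 lower, 8 with the own cell filter and 0 with an estimated correlation.

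Among the other named classes megakaryocyte-like cells had the most called genes. Cluster 11 held 42.5% to 46.5% of them in control and 51.5% to 58.1% in mutant libraries, and the comparison was not made within a cluster. Gem rose there by log2 4.87 (SE 0.274), Hbb-bt by 3.03 (SE 0.185) and Ccnd1 by 1.88 (SE 0.2), while Samd14 fell by 1.33 and Fos by 1.19. Of 18 megakaryocyte priming genes 11 fell and 1 rose (12 and 2 adjusted over the list alone), and of 80 ribosomal protein genes 26 rose and 0 fell (53 and 0 adjusted over the list alone). Of 20 dissociation stress genes 8 fell and 0 rose there (10 and 3 adjusted over the list alone). In all 732 of 10467 genes passed, 391 higher and 341 lower, and DESeq2 called 552. The count was 2035 without control replicate 1, 263 and 307 without control replicates 2 and 3, 385, 240 and 276 without mutant replicates 1, 2 and 3, and 266 with the Xist-negative libraries marked. In MEP-like cells Ccnd1 rose by log2 3.28 (SE 0.316), from 4.16 to 41.2 CPM, and Cd24a, a surface glycoprotein gene, fell by 1.53 (SE 0.132). There 20 of 7994 genes passed, 4 higher and 16 lower, and DESeq2 called 19 (8 higher, 11 lower). The MEP-like count was 616 without control replicate 1, 6 without control replicate 2, 3, 5 and 4 without mutant replicates 1, 2 and 3, and 102 with the covariate. In erythroblast-like cells 16 of 8673 genes passed, 8 higher and 8 lower, among them Apoe, the gene of apolipoprotein E (log2 0.93), and DESeq2 called 22. The erythroblast-like count was 80 without control replicate 1, 5 to 10 without one of the 5 other libraries, and 179 with the covariate. In basophil/mast cell-like cells edgeR called 0 of 6490 genes, with 554 at an unadjusted p under 0.05, and DESeq2 called 10. Without control replicate 1, control replicate 2 or mutant replicate 3 the basophil/mast cell-like count was 18, 2 and 83. In pro-B/pre-B cell-like cells, where mutant replicate 2 had too few cells to enter, 6 of 4965 genes passed, all higher, and DESeq2 called 2. That count was 71 without control replicate 1, 3 without control replicate 2, 20 without mutant replicate 1 and 0 without control replicate 3 or mutant replicate 3, and without a mutant library the spread comes from the controls alone, since 1 mutant library is left.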

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

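The tests in this part were chosen only after the result was seen, apart from the share of sex-linked genes and the comparison within cluster 0.

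The deposited filtered table lacked most cells of a monocyte-like and of a GMP-like cluster in control replicates 2 and 3. The main comparisons between genotypes are made without these cells, and the alternatives with the own cell filter include them. Of the monocyte-like cells the table lacked 93.4% and 97.56% in control replicates 2 and 3, and of the GMP-like cells 71.01% and 60.34%. Rarity of the monocyte-like cells in those libraries is argued against, since they made up at least 1.73% of the cells passing the own filter there, against a mean of 2.21% in the other libraries. Doublets stay open: 10.1% of the missing cells (18 of 179, exact 95% interval 6.07 to 15.4) scored above the 95th percentile of the kept cells, but Scrublet marked 1.2% of the cells passing the own filter in control replicate 2 and 0.0998% in control replicate 3, so its score does not settle this for both. In control replicate 2 the median score was 0.0291 for the 99 missing cells and 0.0282 for the kept cells of that cluster. Over all clusters, missing and kept cells had the same median score in control replicate 2 (0.0282) and in control replicate 3 (0.0289). In control replicate 1 and the mutant libraries the medians were 0.0600 to 0.0798 for missing and 0.0227 to 0.0303 for kept cells. A candidate explanation is the authors' filter on cells, which would have removed them by a criterion other than the ranges of genes and mitochondrial UMIs. The lowest share of 93.4% lies above those of the 4 other libraries, but it defines the pattern and so does not test this explanation. A genotype difference in the GMP-like share stays open, since its exact permutation p with the own cell filter was 0.3 and 3 libraries against 3 cannot go below 0.1.

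Control replicate 1 stood apart from control replicates 2 and 3, and 759 genes separated them in HSC/MPP-like cells, a comparison of 1 library with 2 in which the spread comes from control replicates 2 and 3 and the mutant libraries. Sex-linked genes alone are argued against, since 25 of these genes (3.29%) lie on X or Y. Another mix of clusters is argued against as the whole cause, since in cluster 0 alone the differences kept a median of 76.1% of their size (quartiles 63.9 to 89.6) and 738 of 744 had the same direction. Sex, or another difference between the libraries, may contribute to the genotype calls, which went from 1684 to 335 with the Xist-negative libraries marked, but no mutant library was Xist-negative. That fit compares the mutants with control replicate 1, the only Xist-positive control, so Xist status does not differ between the groups for the 289 of these calls that it kept in the same direction, but 1 control library decides them and another difference of that library stays open. For the 1395 calls it lost, sex and genotype cannot be told apart. A lost call need not mean a lost fold change, but the fold changes of the 1395 lost calls were not compared as a set. Of the 18 lower stem cell genes described below, 12 were still called with the covariate and all 18 kept their direction. Their median log2 fold change was -0.811 with it and -1.17 without it. These genes were picked as lower in the same libraries and most kept the call, so they do not stand for the lost calls. Without control replicate 1 the remaining controls were both Xist-negative and 4494 genes were called.

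In a T and NK cell-like cluster of the own filter the deposited table lacked 67.3%, 33.3% and 50% of the cells in mutant replicates 1, 2 and 3, and 3.18%, 0% and 0% in control replicates 1, 2 and 3.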

How the results depend on the processing

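The parts of classes, the covariate for Xist-negative libraries, the removal of the highest doublet scores and the own cell filter for lists were chosen only after the data were seen. Of 399 values of the main results under an alternative 273 were rated as kept and 126 were not. A count was rated as kept if it stayed within 1.5 times. A class share was rated as kept if its difference kept direction, whatever the change in size. Of 2069 values of named genes 1822 kept direction and side of the threshold, 196 lost and 18 gained the call and 33 turned direction, and of 704 values of single called lists 506 were kept, 177 lost the call and 21 turned direction. For all values below the cause was not tested, except that fewer libraries or cells were used where a library or cluster was left out. What depth limits was not separated from the spread between libraries: of genes changed 1.5-fold edgeR recovered 14.9% in simulated monocyte-like, 31.3% in neutrophil-like, 56.7% in megakaryocyte-like and 58.2% in HSC/MPP-like counts, each simulated at the spread of its own class.

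Same-numbered control and mutant libraries did not deviate together in every class. The correlations for numbers 1, 2 and 3 were 0.226, 0.154 and 0.0264 in HSC/MPP-like and 0.163, 0.204 and -0.00454 in GMP-like cells. They were 0.123, 0.0732 and -0.202 in monocyte-like and 0.129, -0.04 and 0.2 in neutrophil-like cells. Numbers 1 and 2 had the highest correlations of all control and mutant pairs in HSC/MPP-like and GMP-like cells. Whether the numbers pair the libraries stays open. Not every library correlated best with its own number, since in HSC/MPP-like cells control replicate 3 did so with mutant replicate 2 (0.119). With the replicate block the counts of called genes were 2977 in HSC/MPP-like, 137 in GMP-like, 264 in neutrophil-like, 86 in MEP-like, 38 in erythroblast-like, 2 in basophil/mast cell-like and 61 in pro-B/pre-B cell-like cells, and 108 in cluster 18 and 45 in cluster 21.

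With the Xist-negative covariate the counts were 335 in HSC/MPP-like, 13 in monocyte-like, 11 in neutrophil-like, 266 in megakaryocyte-like, 102 in MEP-like, 179 in erythroblast-like and 1 in basophil/mast cell-like cells, and 196, 161, 18 and 19 in clusters 3, 6, 18 and 21, and 0 fetal members passed. Called lists turned direction there in GMP-like cells (self-renewal, adjusted p = 0.947, and lymphoid priming, 0.726), in monocyte-like cells (primary granule, 0.0594, and G2/M, 0.916) and in neutrophil-like cells (type I interferon, 3.83e-08). Of lists not called without the covariate, interferon gamma was called lower with it in HSC/MPP-like (adjusted p = 4.83e-05, without it 0.511), GMP-like (1.78e-17, without it 0.349) and neutrophil-like cells (3.16e-14, without it 0.878), and turned direction in the first and the last. Lymphoid priming (higher, 0.0185) and the unfolded protein response (lower, 0.0427) in HSC/MPP-like and primary granule in GMP-like cells (lower, 0.0359) were also called after a turn. Genes that turned direction there were Ptpn11 (log2 -0.14 in HSC/MPP-like, -0.066 in GMP-like and -0.25 in neutrophil-like cells), Hmga2 (-0.12) and Arid3a (-0.15).

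Without a count filter the counts were 2533 in HSC/MPP-like, 287 in GMP-like, 40 in monocyte-like and 461 in neutrophil-like cells. DESeq2 gave 176 in GMP-like, 17 in monocyte-like, 50 in neutrophil-like, 10 in basophil/mast cell-like and 2 in pro-B/pre-B cell-like cells, 754 in cluster 6 and 18 in cluster 23, and 0 fetal members. With the own cell filter the counts were 25 in monocyte-like and 13 in neutrophil-like cells, and 8 lists were called in neutrophil-like cells. Called lists that turned direction there were secondary granule in GMP-like cells (adjusted p = 0.00803), interferon gamma (0.309), NF-kB (0.928), S-phase (0.0197), G2/M (0.232) and cholesterol (0.164) in monocyte-like cells and ribosomal proteins in neutrophil-like cells (0.0022). Hmga2 (log2 -0.082) in HSC/MPP-like and Camp (-0.55) in GMP-like cells did so too. The primary granule list in GMP-like cells, not called among the kept cells (camera adjusted p = 0.509), was called lower there after a turn (0.00106). Leiden resolution 2 gave 1 gene in monocyte-like cells, and resolution 0.5 gave 10 in neutrophil-like cells and Hmga2 at log2 -0.13. With doublets kept 7 genes were called in neutrophil-like cells. Without the highest doublet scores 22 were called in monocyte-like and 17 in neutrophil-like cells, with Hmga1 at log2 -0.033 and Arid3a at -0.020 in HSC/MPP-like and Ptpn11 at 0.13 in monocyte-like cells. Cluster 10 alone gave 3 genes in monocyte-like cells and Ptpn11 at 0.13.

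Without cluster 16 there were 1048 genes in HSC/MPP-like cells, with Hmga2 at log2 -0.033. Cluster 0 alone gave 159, with lists turned for quiescence (adjusted p = 0.876), self-renewal (0.845), primary granule (0.569), megakaryocyte priming (0.704), S-phase (3.75e-09), G2/M (0.044) and glycolysis (0.905), and with Mllt3 at log2 0.435, Ccnb2 at -0.24, Rrm2 at -0.78, Hmga2 at -0.29 and Hmga1 at -0.21. Of lists not called in the whole class, cluster 0 alone had type I interferon called higher by camera (adjusted p = 1.57e-09, in the class 0.699). Interferon gamma (5.02e-06, in the class 0.511) and MHC class II (2.13e-05, in the class 0.269) were also called higher there. The estimated correlation was not run in cluster 0. Cluster 2 alone gave 261, with Mllt3 at log2 0.29, Rrm2 at -0.18, Hmga2 at -0.61 and Hmga1 at -0.10. With clusters 3 and 6 added Ccnb2 was at log2 -0.29 and Hmga2 at -0.23. An estimated correlation called 0 lists in each of the HSC/MPP-like, GMP-like, monocyte-like and neutrophil-like classes, and fry, which does not compare a list with other genes, called 5, 0, 0 and 1.

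Leaving out each library in turn gave 362 to 4494 genes in HSC/MPP-like, 17 to 748 in GMP-like, 0 to 1270 in monocyte-like, 2 to 184 in neutrophil-like, 240 to 2035 in megakaryocyte-like, 3 to 616 in MEP-like, 5 to 80 in erythroblast-like, 0 to 83 in basophil/mast cell-like and 0 to 71 in pro-B/pre-B cell-like cells. It gave 167 to 2121 in cluster 3, 413 to 2009 in cluster 6, 18 to 422 in cluster 18, 3 to 43 in cluster 21 and 0 to 34 in cluster 23, 0 to 765 for the difference between HSC/MPP-like and GMP-like effects and 0 to 2 fetal members. The highest count came without control replicate 1, except in basophil/mast cell-like cells and cluster 21 (mutant replicate 3) and cluster 23 (mutant replicate 1). List adjusted p ran from 5.42e-09 to 0.161 for interferon gamma in monocyte-like and from 5.09e-11 to 0.825 for type I interferon in neutrophil-like cells. Ptpn11 ran from log2 -0.021 to 0.18 in HSC/MPP-like, -0.29 to 0.063 in monocyte-like and -0.020 to 0.33 in neutrophil-like cells, Igf2bp2 from -0.020 to 0.22, Hmga2 from -0.26 to 0.32 and Arid3a from -0.044 to 0.21.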

Other observations

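The tests of explanations in this part and the counts over other splits of the libraries were chosen only after the result was seen.

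Cycling progenitors outside the named classes also differed between genotypes. In cluster 3, led by histone genes, Gem rose by log2 4.65 (SE 0.259), Hbb-bt by 3.89 (SE 0.258) and Ccnd1 by 2.27 (SE 0.198), while Ifitm1, Tnfsf13 and Serpinf1 fell by 2.02, 2.02 and 1.99. Of its 10886 tested genes 716 passed, 373 higher and 343 lower, and DESeq2 called 613 (384 higher, 229 lower). In cluster 6, led by Ube2c and Cenpf, Ccnd1 rose by log2 3.48 (SE 0.213) and Dntt, the terminal transferase of lymphoid progenitors, fell by 2.86 (SE 0.167) from 148 to 19.9 CPM. Of its 10074 genes 1201 passed, 792 higher and 409 lower, and DESeq2 called 754 (556 higher, 198 lower). Of 80 ribosomal protein genes 56 rose and 0 fell in cluster 6 (67 and 0 adjusted over the list alone), of 31 MYC genes 27 rose (29 adjusted over the list alone), and of 14 lymphoid priming genes 6 fell and 0 rose (7 and 1 adjusted over the list alone). In cluster 3 30 ribosomal protein and 13 MYC genes rose and 0 fell (57 and 24 risen adjusted over the list alone). S-phase genes, of which 9 rose and 0 fell in HSC/MPP-like cells, ran the other way: 7 of 32 fell and 0 rose in cluster 3 (14 and 0 adjusted over the list alone), and 5 of 30 fell and 2 rose in cluster 6 (6 and 2). Of 35 G2/M genes 8 rose and 0 fell in cluster 3 (10 and 1) and 3 rose and 2 fell in cluster 6 (3 and 2). Dissociation stress genes, which respond to handling, fell in 10 of 19 with 1 risen in cluster 6 (10 and 2 adjusted over the list alone) and in 8 of 20 with 0 risen in cluster 3 (10 and 2). Without control replicate 1 the counts in clusters 3 and 6 were 2121 and 2009, without control replicate 2 167 and 430, without control replicate 3 361 and 671, and without mutant replicates 1, 2 and 3 290 and 636, 326 and 742, and 205 and 413. With the Xist-negative libraries marked they were 196 and 161.

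In cluster 18, led by Dntt and Flt3, Hbb-bt rose by log2 4.66 (SE 0.504) and Ifitm1 fell by 3.40 (SE 0.426), and 47 of 7492 genes passed, 23 higher and 24 lower, against 43 higher and 13 lower by DESeq2. The count was 422 without control replicate 1, and 18, 20 and 23 without control replicate 2, mutant replicate 2 and mutant replicate 3, and 18 with the Xist-negative libraries marked. In cluster 21, led by the T cell genes Trbc2 and Cd3g, mutant replicate 1 had 18 cells and did not enter, and the kept cells lack 33.3% to 67.3% of such cells in the mutant libraries as given above. There 9 of 3877 genes passed, and Klri2, a killer cell lectin-like receptor gene, had 66 UMIs in control and 0 in mutant libraries, a call that DESeq2 did not make (adjusted p = 0.0604) and that was lost without any one control library or mutant replicate 2. The cluster 21 count was 4, 3 and 5 without control replicates 1, 2 and 3, 30 and 43 without mutant replicates 2 and 3, where 1 mutant library is left and the spread comes from the controls alone, and 19 with the Xist-negative libraries marked. In cluster 23, led by Cd74 and Siglech, edgeR called 0 of 3113 genes, with 300 at an unadjusted p under 0.05, and DESeq2 called 18, while without control replicate 1, control replicate 3 or mutant replicate 1 edgeR called 25, 1 and 34. In HSC/MPP-like cells Hbb-bt had 54.9, 29.6 and 30.6 CPM before scaling in control replicates 1, 2 and 3 and 401, 525 and 525 CPM in mutant replicates 1, 2 and 3, while Hbb-bs had 2.64, 15.5 and 5.87 CPM and 2.15, 2.60 and 5.78 CPM. In erythroblast-like cells Hbb-bt had 39.5, 194 and 281 CPM in control and 6.84, 47.2 and 158 CPM in mutant replicates 1, 2 and 3.

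Of 53 measured genes in the self-renewal list, the quiescence list or the markers of the class, 18 were lower in mutant HSC/MPP-like cells. A smaller share of cluster 16 is argued against for 10 of them, which were still lower without that cluster, and as the whole cause for Runx1, Btg1, Foxo3 and Klf4, picked after their values were seen, which lost the call there but kept 90% to 106% of their fold change. It stays open for the other 4, with a median of 49.7% left (quartiles 40.6 to 50). Fewer cells of cluster 0 and more of cluster 2 is argued against for the 4 genes still lower in cluster 0 alone, among them Procr (log2 -0.95), Junb (-0.58) and Ifitm1 (-1.48). As the whole cause it is also argued against for Foxo3, which was not called there but had 120% of its fold change left. For the 11 other genes tested there it stays open, with a median of 30.1% of the fold change left (quartiles 11.5 to 45.8). The lower values of this part may therefore come in part from the mix of clusters, and a change of genotype within cells was not separated from it.

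The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For the counts of called genes, 1 split, the real one, reached the real count in HSC/MPP-like cells (1684, highest other 0), GMP-like cells (51, highest other 2), neutrophil-like cells (4, highest other 0), megakaryocyte-like cells (732, highest other 0), MEP-like cells (20, highest other 0) and erythroblast-like cells (16, highest other 3), and in clusters 3 (716, highest other 2), 6 (1201, highest other 0) and 18 (47, highest other 3). All 10 splits reached the real count of 0 in monocyte-like cells (highest other 2), basophil/mast cell-like cells (highest other 3) and cluster 23 (highest other 0), for the difference between HSC/MPP-like and GMP-like effects (highest other 0) and for class shares by edgeR (highest other 0). For the counts of called lists, 2 splits reached the real count in HSC/MPP-like cells (16, highest other 17), 5 in GMP-like cells (12, highest other 15), 2 in monocyte-like cells (15, highest other 16) and 3 in neutrophil-like cells (13, highest other 14).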
